A study of Mus musculus with 6 samples.

How the data were processed

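Cytoplasmic polyA RNA was sequenced from C2C12 cells, a mouse myoblast line that stops dividing and forms multinucleated myotubes when serum is withdrawn. The cells carried a lentiviral short hairpin against Kap1 (the protein also called TRIM28, encoded by Trim28) or, as the control, against luciferase. Proliferating myoblasts (MB) and cells after 48 hours in differentiation medium with horse serum and insulin, transferrin and selenium (MT) were profiled. Groups and replicate numbers were taken from the sample titles, which gave 2 MB control, 2 MB knockdown, 1 MT control and 1 MT knockdown libraries. Nothing in the labels says that the MB replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

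The deposited values are whole-number read counts per Ensembl gene, 37991 genes in each of the 6 libraries. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.11 to the mm9 mouse genome and counted with HTSeq. The annotation release, the counting mode, the strand setting and the library chemistry are not given in the sources used here. Genes that overlap an antisense partner, and members of families with near-identical copies, are therefore given as uncertain. Lines that name no gene were left out of library sizes and tests. Reads outside any gene were 5.18% to 8.07% of the reads assigned to genes, to no gene or to more than 1 gene, and ambiguous reads were 2.81% to 2.93%. Gene symbols came from a mouse annotation of a later genome build, matched on the Ensembl identifier. For the check of neighbouring genes, gene order along chromosomes came from a RefSeq gene table of a later build, matched by symbol. Coordinates were not used otherwise. Symbols were found for 32919 identifiers, which held 99.04% of the counts. The total count on genes ranged from 36247530 to 49839994 per library, and 3 counts, the floor used where a gene had none, correspond to 0.0602 to 0.0828 CPM (counts scaled to library size). Intervals of ratios are at the 95% level, and intervals and floors cover counting error only.

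Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersion, TMM scaling, filterByExpr by group). All 6 libraries entered 1 fit with a mean per group. The filter left 16472 genes, 15619 of them with a symbol, and TMM factors ran from 0.972 to 1.07. The 5 contrasts were knockdown against control in MB, knockdown against control in MT, MT against MB in control cells, MT against MB in knockdown cells, and the interaction, which is the MT knockdown effect minus the MB knockdown effect. P-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. With 1 MT library per arm, the MT contrasts have no replicate check of their own and assume that the lone libraries vary as the MB libraries do.

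A second fit added a term for batch. The deposited files of replicate 1 of both MB groups and of both MT libraries carry a mark in their names that the files of replicate 2 lack. The former were therefore taken as batch 1 and the latter as batch 2. What the mark stands for is not given in the sources used here. The fit without a batch term has 2 residual degrees of freedom and a common biological coefficient of variation of 32.9%, the fit with it 1 residual degree of freedom and 9.74%. Both fits were written down before the data were examined, as were the gene lists, the rule for named genes and the alternatives, except where an alternative is said to have been added. The fit without a batch term was chosen as the primary one and called no gene in any contrast. Describing the genes called with the batch term, and applying the rule for named genes to that fit as well, was decided after this had been seen. In that fit both differentiation contrasts share the estimate of the batch difference.

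Named genes were chosen as follows. For both knockdown contrasts and control differentiation, the 10 genes with the largest log2 change each way were taken among those past the threshold with a mean of at least 1 CPM and with no overlap between the groups' libraries. The interaction took 5 each way without the last criterion. Where no gene passed, the 5 with the smallest p each way were taken. Up to 4 members of each described list with the smallest p, Trim28, and a fixed set of 14 myogenic and cell cycle genes were added. Not every gene so chosen is printed. Fold changes of genes with 0 to 3 counts in a group depend on the prior count, so such genes are given as ratios of summed counts with an exact interval, as a lower bound, or as CPM.

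Gene lists were tested with camera (limma 3.58.1), on the counts with the dispersions of the fit and with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over 115 tests (23 lists in 5 contrasts). Each test was repeated with the correlation estimated from the data, under which 0 of the 35 called tests passed, so every list call below rests on the preset value. List tests are from the fit without a batch term unless stated. Log2 changes of genes and counts of rising and falling list members are from the fit with it, and values without a given library are from the fit without it. Because the MT groups have 1 library each, a list's median difference in log2 CPM (prior count 2) between single libraries was also placed among the medians of 10000 random lists of the same size matched on expression, which describes these libraries only. The lists were KAP1 and its partners, myogenic regulators and cofactors, the contractile apparatus and muscle metabolism, myoblast fusion and adhesion, the undifferentiated myoblast state, cell cycle and DNA replication, cell cycle exit, p53 targets, imprinted genes, the interferon response, germline genes, extracellular matrix and fibroblast markers, and smooth muscle markers. Further lists held osteoblast and chondrocyte, adipocyte, neuronal, and blood and endothelial markers, nuclear-retained RNAs, mitochondrial and oxidative phosphorylation genes, the unfolded protein response and stress, histone genes, control genes, and all genes named Zfp with a number.

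The procedure was tested on simulated counts for the 16472 genes with the observed means and library sizes. With replicates alike, the fit without a batch term recovered 91 of 100 genes changed 2-fold and 99 of 100 changed 4-fold in the MB knockdown contrast, and 84 and 99 of 100 in the MT contrast. With a batch difference like the observed one, that fit recovered 0 of 100 at either size in both contrasts. The fit with the batch term recovered 89 and 100 of 100 in MB and 82 and 100 of 100 in MT. Of the calls made with the batch term in that simulation, 9.57% in MB and 11.2% in MT were false, above the nominal level. These counts were drawn from the model of the fit with the batch term, with 100 genes changed at each size. No further variation between MT cultures was simulated, so these shares are not error rates of the real calls. With the batch difference, a simulated list of 50 moved genes gave p = 4.66e-115 in MB with the preset correlation and p = 0.00127 with the estimated one. An unmoved list gave p = 0.559 with the preset correlation.

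The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, total library size, no filter on low counts, the batch term, the MB libraries alone, and each MB library left out in turn. The batch term combined with another tool, scaling or filter, or with the MT libraries placed in batch 2, was added after seeing the data. A symbol is lacking for 2 genes that the rule named, which are not reported here.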

Results

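The series asks how KAP1, a scaffold protein that joins chromatin-modifying enzymes to transcription factors, bears on gene expression when C2C12 myoblasts differentiate. Polyadenylated cytoplasmic RNA was compared between control and Kap1 knockdown cells, as proliferating myoblasts (MB, 2 libraries each) and after 48 hours of differentiation (MT, 1 library each). The libraries held between 36247530 and 49839994 counts on genes, with 19386 to 21351 genes detected. The 10 most abundant genes took 4.93% to 7.31% of the counts. In a principal component analysis of log2 CPM, component 1 (54.7% of variance) placed the MT control library at 120.7, the MT knockdown library at 50.7 and the MB libraries between -59.13 and -34.88. Component 2 (22.6%) separated replicate 2 of both MB groups (-54.54 and -51.01) from replicate 1 (36.29 and 51.24), and component 3 held 14.9%.

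Trim28, the gene encoding KAP1, was lower in every knockdown library than in every control library. In CPM it stood at 596 and 428 in MB control, 150 and 102 in MB knockdown, 394 in MT control and 114 in MT knockdown. With the batch term, its log2 change was -2.03 in MB (SE 0.0997, adjusted p = 2.64e-05, edgeR quasi-likelihood, Benjamini-Hochberg) and -1.78 in MT (SE 0.14, adjusted p = 1.7e-05). Without the batch term the MB value was -2.02, with unadjusted p = 0.00181 and adjusted p = 1 (edgeR), and it ranged from -2.33 to -1.76 when single MB libraries were left out.

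The MB replicates differed from each other in the same genes in both groups. Myog, the transcription factor that starts terminal muscle differentiation, was at 1.28 CPM in replicate 1 and 33.8 CPM in replicate 2 of the control, and at 0.676 and 14.3 CPM in the knockdown. Tagln, an actin-binding protein of smooth muscle, went the other way, from 296 to 85.1 CPM and from 928 to 190 CPM. So did Cnn1, a smooth muscle calponin, from 37.8 to 5.25 CPM and from 87.2 to 11 CPM. The imprinted noncoding RNA H19, which accumulates in differentiating muscle, was at 199 and 1770 CPM in the control and 213 and 2741 CPM in the knockdown. Across the 16472 tested genes, which are not independent replicates, the replicate 2 minus replicate 1 differences of control and knockdown correlated with r = 0.762 (Spearman's rho 0.681). Replicate number went with a mark in the names of the deposited files, and this difference entered the spread on which tests without a batch term rest.

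**Figure D1:**
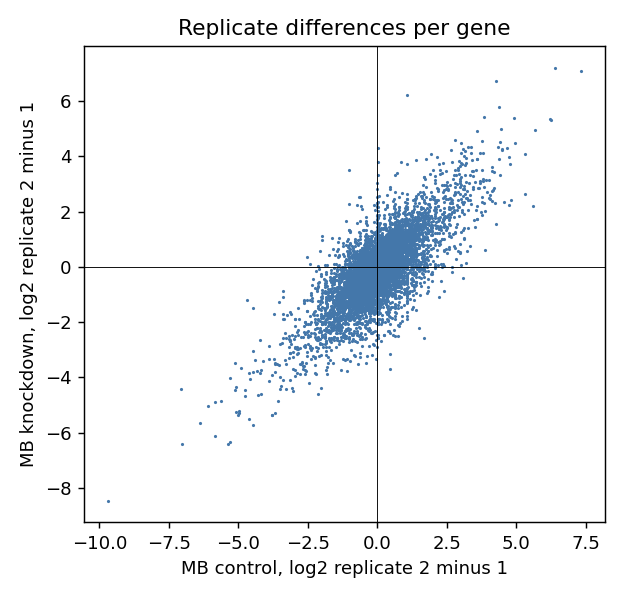
Difference between the MB replicates, 1 point per gene. The x axis gives log2 CPM of replicate 2 minus replicate 1 in control cells and the y axis the same difference in knockdown cells.

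In proliferating knockdown cells, genes for the extracellular matrix and for the smooth muscle cytoskeleton were higher than in control cells and cell cycle genes were slightly lower, each as a group. Several genes with almost no counts in control cells were readily counted after knockdown, among them a liver protease inhibitor and members of a vomeronasal receptor family. Lower genes included Sprr1a, a precursor of the epithelial cornified envelope, Il33, an alarm cytokine, and Grem1, a secreted antagonist of bone morphogenetic proteins. No gene passed in this comparison without a batch term (edgeR quasi-likelihood, Benjamini-Hochberg: 0 genes, smallest adjusted p = 1), while 454 genes had unadjusted p under 0.05 (335 higher, 119 lower) and DESeq2 called 50 (37 higher, 13 lower). The edgeR fit with the batch term called 632, of which 412 rose and 220 fell, with 211 and 71 of these changing at least 2-fold. In simulated data with a batch difference, 9.57% of such calls were false, but those counts followed the model of the fit, so this is not the error rate here.

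Among the genes that fell in MB with the batch term were Sprr1a (15.8 and 15.5 CPM in control, 0.95 and 0.534 in knockdown, log2 change -4.40, adjusted p = 3.12e-05, edgeR) and Il33 (-3.50). Lrrc4c, a neuronal adhesion protein, fell as well (-3.47, from 9.87 and 10 CPM to 1.06 and 0.743). These 3, together with Ttll11, a tubulin-modifying ligase (-1.88), and Ank, a pyrophosphate transporter (-1.01), also had the smallest unadjusted p among lower genes without the batch term, where none passed. Grem1 fell by 2.53 on the log2 scale (adjusted p = 7.92e-05, edgeR with batch term). In the fit without it Grem1 stood at -3.56 without MB_shKap1 replicate 1 and -1.63 without MB_shCtrl replicate 1. Also lower were Blnk, a B cell signalling adaptor (-2.52, and -1.90 without MB_shCtrl replicate 1), and Serpinb2, an inhibitor of plasminogen activators (-2.51, and -1.82 without that library). Has1, a hyaluronan synthase, fell by 2.34, between -3.50 without MB_shKap1 replicate 1 and -0.98 without MB_shCtrl replicate 1. For Sprr2k the change was -1.96, between -3.57 and -0.77 without the same libraries. The muscle LIM protein gene Csrp3 had 19 counts in control and 2 in knockdown, a ratio of 0.0942 (interval 0.0106 to 0.391), with most control counts in replicate 2 (0.429 CPM, against 0.0484 in replicate 1).

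Genes that rose in MB with the batch term included Fat4, a giant cadherin of planar polarity (33.4 and 36.7 CPM in control, 83.6 and 81.8 in knockdown, log2 change 1.24, adjusted p = 0.000169, edgeR). Slc1a6, a glutamate transporter, rose by 1.82 and Col11a1, a cartilage collagen, by 2.45. The lectin gene Cd209c went from 1.74 and 3.48 CPM to 19.07 and 70.4 CPM (log2 change 3.95, adjusted p = 0.000949, edgeR), and the hypoxia-responsive factor Epas1 rose by 3.91. Within the pairs of replicates 1 and 2, Cd209c was higher by 3.42 and 4.32 on the log2 scale and Epas1 by 2.21 and 4.46. The predicted genes Gm11331 (4.68, with 3.26 and 5.39 within pairs) and Gm13988 (4.01, with 3.16 and 4.54) rose as well, but such genes can share reads with relatives and remain uncertain. Kank4, a cytoskeletal adaptor, had 2 counts in control and 890 in knockdown (ratio 398, interval 110 to 3290), though with 0.95 CPM in knockdown replicate 1 and 19.6 in replicate 2. Ratios of the same kind were 201 (35.8 to 7990) for Cdhr2, a cadherin of the intestinal brush border, and 65.4 (22.1 to 319) for Serpina1d, a liver antitrypsin. They were 60 (10.4 to 2400) for Ggt5, a glutamyltransferase, and 27.8 (4.63 to 1130) for the antiviral gene Oas1a, mostly from replicate 1 (0.591 CPM, against 0.0696 in replicate 2). The vomeronasal receptor gene Vmn2r96 and Vmn2r-ps119, a pseudogene of the same family by its name, had ratios of 18.8 (7.08 to 70.6) and 41.5 (17.5 to 129). Like Serpina1d they belong to families whose members can share reads, so the assignment to a member is uncertain.

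Extracellular matrix genes were higher in MB knockdown (camera, adjusted p = 1.99e-08; 0.899 with an estimated correlation). Of 43, 35 lay above 0, and with the batch term 14 rose and 0 fell (19 and 0 adjusted over the list alone). The collagens Col12a1 (log2 change 0.73), Col1a1 (0.72) and Col6a1 (0.69), which build the fibrillar and microfibrillar matrix, were among them. The list's median log2 difference was 0.438 in the replicate 1 pair and 0.26 in the replicate 2 pair, each at percentile 100 of random lists. Osteoblast and chondrocyte markers, not called (camera, adjusted p = 0.198), had medians of 0.679 (percentile 100) and 0.192 (97.7), the latter -0.0831 with low counts set to 3. Postn, a matricellular protein of wound repair, rose by 1.36, between 0.57 without MB_shKap1 replicate 1 and 2.01 without MB_shCtrl replicate 1. Smooth muscle markers were higher as a list (camera, adjusted p = 0.0283; 0.899 with an estimated correlation), with 6 of 11 rising and 0 falling, and the same 6 and 0 adjusted over the list alone. Lmod1, an actin filament nucleator, rose by 2.17, Tagln by 1.41, Cnn1 by 1.15 and the smooth muscle actin Actg2 by 0.71. The median log2 difference of the list was 0.63 in the replicate 1 pair and 0.505 in the replicate 2 pair, each at percentile 100 of 10000 random lists. The list call was lost, with the opposite direction, when a library was left out and the batches became unbalanced (camera adjusted p = 0.984 without MB_shCtrl replicate 2 and 0.944 without MB_shKap1 replicate 1). Leaving out MB_shKap1 replicate 1 gave 0.80 for Lmod1, -0.97 for Cnn1, -0.00211 for Tagln and -0.40 for Actg2, and leaving out MB_shCtrl replicate 1 gave 3.34, 3.23, 2.72 and 1.79.

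Genes of the interferon response, the program cells switch on against viruses, were higher in MB knockdown as a list (camera, adjusted p = 2.95e-07; 0.899 with an estimated correlation). With the batch term 9 of 55 rose and 0 fell (16 and 0 adjusted over the list alone). Among them were Iigp1, a GTPase (log2 change 2.28, and 1.30 without MB_shKap1 replicate 1 or 4.17 without MB_shCtrl replicate 1), Trim30a (0.97) and the membrane protein Ifitm3 (0.60). This rested on replicate 1. The list median was 0.716 in that pair and 0.0534 in the replicate 2 pair, and without MB_shKap1 replicate 1 the direction reversed (camera adjusted p = 0.504). Cell cycle genes were lower (camera, adjusted p = 4.27e-09; 0.899 with an estimated correlation). Of 72, 65 lay below 0, with pair medians of -0.268 and -0.0884, and 0 rose and 2 fell with the batch term (0 and 8 adjusted over the list alone). The 2 were Cenpf, a kinetochore protein (-0.61), and Ect2, a cytokinesis factor (-0.56), and the list stood at 0.0668 without MB_shCtrl replicate 1 (camera). Zinc finger genes named Zfp, many of which encode the DNA-binding partners of KAP1, were slightly higher (camera, adjusted p = 0.0259; 0.899 with an estimated correlation). Their median was 0.0806 over 329 genes, with 6 rising and 0 falling (3 and 0 adjusted over the list alone). Zfp977 (1.70), Zfp78 (1.62) and Zfp110 (0.66) rose. The list call was lost without MB_shCtrl replicate 1 (0.354), MB_shKap1 replicate 1 (0.0809) or MB_shKap1 replicate 2 (0.203, camera).

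Of the muscle regulators, Myog fell by 1.18 on the log2 scale in MB (adjusted p = 0.00123, edgeR with batch term). Because its replicates differ so widely, it stood at -4.69 without MB_shKap1 replicate 2 and at 2.54 without MB_shCtrl replicate 2. Myod1, the factor that commits cells to muscle, was at 11.9 and 31.8 CPM in control and 3.44 and 20.7 CPM in knockdown (log2 change -1.12, adjusted p = 0.409, edgeR with batch term). It ranged from -2.67 without MB_shKap1 replicate 2 to 0.01 without MB_shCtrl replicate 2. Values past the threshold were not reached for Myf5, a myoblast determination factor, at 83.5 and 70.3 CPM in control and 48.9 and 92.8 in knockdown. The same holds for the proliferation marker Mki67, at 582 and 713 CPM and 348 and 634 CPM.

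**Figure D2:**
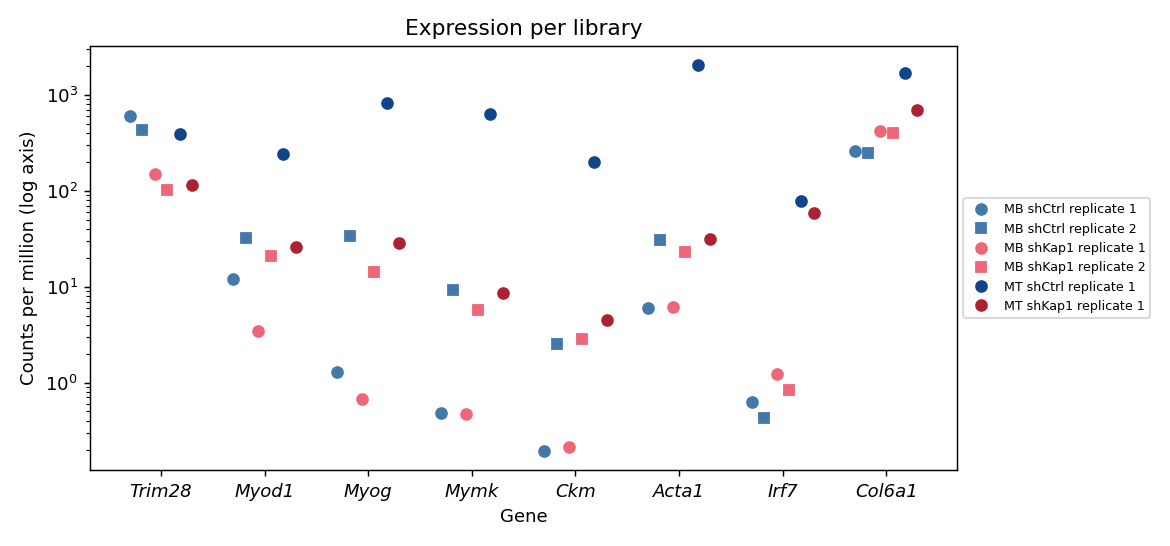
Expression of 8 genes in each library, in CPM on a log axis. Circles are replicate 1 and squares replicate 2, blue shades are control and red shades knockdown cells, and the darker shade of each is MT.

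After 48 hours of differentiation, the knockdown library lacked most of the muscle program seen in the control library. Genes of the sarcomere, the contractile unit of muscle, of fusion and of cell cycle exit were lower, and so were matrix and interferon genes. Cell cycle genes were slightly higher, with a median no larger than that of genes often used as controls. Myog stood at 818 CPM in control and 28.2 CPM in knockdown, Mymk, the membrane protein that fuses myoblasts, at 627 and 8.5 CPM, and Casq2, a calcium store protein, at 451 and 4.91 CPM. Each MT group is 1 library, so no replicate check exists and the tests assume that the lone libraries vary like the MB ones. Without a batch term edgeR quasi-likelihood called 0 genes (Benjamini-Hochberg, smallest adjusted p = 0.457), 1383 had unadjusted p under 0.05 (565 higher, 818 lower) and DESeq2 called 368 (60 higher, 308 lower). The batch term fit of edgeR called 3344 (1498 rose, 1846 fell), of which 567 and 980 changed at least 2-fold. In simulated data 11.2% of such calls were false. Those counts followed the model of the fit without added variation between MT cultures, so this share is not the error rate here. The share of calls that rose was 44.8% with TMM scaling and 62.7% with total library size.

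Contractile and muscle metabolism genes were lower in the MT knockdown library (camera, adjusted p = 2.05e-29; 0.899 with an estimated correlation). Of 78, 69 fell and 0 rose with the batch term (72 and 0 adjusted over the list alone). The median log2 difference was -5.00, at percentile 0 of 10000 random lists matched on expression, or -5.05 with counts under 3 set at 3. Log2 changes were -6.52 for Casq2, -6.51 for the fast troponin Tnni2, -6.09 for Ttn, the giant elastic protein titin, and -6.01 for the skeletal actin Acta1 (2039 and 31.6 CPM). They were -5.49 for Ckm, muscle creatine kinase (200 and 4.44 CPM; adjusted p = 3.56e-08, edgeR with batch term), and -5.11 for the troponin Tnnt3. Larger changes belonged to the myosin heavy chains Myh8 (-8.13) and Myh4 (-7.26) and to Apobec2, a muscle deaminase (-7.15). Dhrs7c, a reductase of the sarcoplasmic reticulum, had 1168 counts in control and 4 in knockdown, and Actn2, which anchors thin filaments, 1382 and 5. These are ratios of 233 (interval 90.9 to 858) and 221 (94.5 to 682) of control over knockdown. Such ratios were 178 (69.3 to 655) for Myh13, 177 (75.5 to 545) for Myoz2, a calcineurin-binding protein of the Z disc, and 394 (135 to 1910) for Csrp3. They were 176 (48.4 to 1460) for Dbh, an enzyme of noradrenaline synthesis, and 640 (114 to 25300) for Fgfbp1, which releases growth factors from the matrix. The intermediate filament gene Des fell less, by 1.27 (1244 and 517 CPM).

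Lower genes with the smallest unadjusted p in MT without the batch term, none of them passing, were Pygm, muscle glycogen phosphorylase, Itgb1bp2, a muscle chaperone also called melusin, Cacnb1, a calcium channel subunit, Lzts3 and Rap1gap2. Their log2 changes with the batch term were -5.61, -6.03, -3.64, -2.58 and -4.53. Among regulators, Myog fell by 4.86 (adjusted p = 4.29e-08, edgeR with batch term). Mef2c, a partner of the myogenic factors, fell by 6.28 (22.3 and 0.284 CPM), Mef2a by 1.98 and Mef2d by 1.34. Myod1, at 239 and 25.7 CPM, did not pass (log2 change -3.22, adjusted p = 0.09, edgeR with batch term), and neither did the embryonic myosin Myh3 at 2197 and 13.2 CPM (-7.38, adjusted p = 0.052). Nor did Myf5, at 35.8 and 77.1 CPM (1.10, adjusted p = 0.406, edgeR), or Id3, an inhibitor of myogenic factors, at 78 and 137 CPM (0.81, 0.124). Mki67 at 197 and 230 CPM (0.22, 0.502) and Myf6 at 0.33 and 0.207 CPM (-0.67, 0.563; edgeR) stayed above the threshold too. The list of myogenic regulators had adjusted p = 0.0673 in this comparison without the batch term and 0.0283 with it (camera, lower), and 0.818 with it and an estimated correlation.

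Fusion and adhesion genes were lower as a list (camera, adjusted p = 0.00861; 0.899 with an estimated correlation). Their median of -0.546 was at percentile 0 of random lists, with 11 of 26 falling and 1 rising (12 and 3 adjusted over the list alone). The fusion proteins Mymk (log2 change -6.21) and Mymx (-5.23, 90.5 and 2.4 CPM), the protease Adam12 (-2.20), and the adhesion molecules Ncam1 (-1.33), Jam3 (-0.92) and Dysf (-0.86), the last a membrane repair protein, fell. The integrin Itga3 rose by 1.70. The fusion list stood at 0.0965 with no filter on low counts (camera). Cell cycle exit genes were lower (camera, adjusted p = 0.00861; 0.899 with an estimated correlation, and 0.0937 with no filter). Their median was -0.43 (percentile 0.04 of random lists), with 7 of 15 falling and 2 rising, the same adjusted over the list alone. The kinase inhibitors Cdkn1c (-3.91) and Cdkn1a (1719 and 346 CPM, -2.31, adjusted p = 0.0388, edgeR with batch term), the cyclin Ccnd3 (-1.77) and the retinoblastoma gene Rb1 (-1.29) fell, and Gas2, a growth arrest protein, rose by 1.62. Cell cycle genes were higher as a list (camera, adjusted p = 0.0283; 0.899 with an estimated correlation, 0.0726 with no filter, 0.108 with the batch term). Their median of 0.153 was at percentile 100 of random lists, with 25 of 72 rising and 10 falling (27 and 11 adjusted over the list alone). Genes often used as controls, not called here as a list, had a median of 0.183 (percentile 96 of random lists). The cell cycle median was no larger than theirs. Ccnb2, a mitotic cyclin (1.20), Cdc20, an activator of the anaphase-promoting complex (1.17), and the kinesin Kif20a (1.02) rose, and E2f2, a transcription factor of the cycle, fell by 2.65.

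Interferon genes were lower in the MT knockdown library as a list (camera, adjusted p = 0.045; 0.915 with an estimated correlation, 0.0577 with DESeq2 size factors, 0.168 with no filter). Their median of -0.29 was at percentile 0 of random lists, and 15 of 55 fell while 0 rose (20 and 0 adjusted over the list alone). Log2 changes were -2.15 for the antiviral synthetase Oas2 and -1.62 for the chemokine Cxcl10. Matrix genes were lower (camera, adjusted p = 0.0259; 0.899 with an estimated correlation, 0.0628 with no filter). Their median was -0.398, at percentile 0 of random lists, with 18 of 43 falling and 4 rising (22 and 6 adjusted over the list alone). The matrix protease Mmp9 fell by 3.47, and the collagen chains Col6a2 and Col6a1, which had risen in MB, fell by 1.68 and 1.28. Zfp genes were higher (camera, adjusted p = 0.00147; 0.899 with an estimated correlation). Their median was 0.218, at percentile 100 of random lists, with 50 of 329 rising and 12 falling (37 and 11 adjusted over the list alone). Genes often used as controls had a median of 0.183. Zfp36, which destabilises messenger RNAs and is not a partner of KAP1, rose by 1.98, while Zfp568 and Zfp106 fell by 1.41 and 1.15.

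Genes higher in the MT knockdown library were partly the same near-silent genes as in MB. Vmn2r-ps119 had 1 count in control and 167 in knockdown (ratio 209, interval 37 to 8300), and Kank4 4 and 264 (82.6, 31.9 to 305). Serpina1d had 7 and 462 (82.6, 39.7 to 206), and Cdhr2 0 and 46, at least 19.2-fold, with the same doubt about related genes. Vmn2r96 and Gm17043 had ratios of 16.6 (9.01 to 34) and 62.5 (10.7 to 2520). Together with Lgr4, a Wnt-enhancing receptor (log2 change 1.58), Tkt, a pentose phosphate enzyme (1.43), and Gm8113 (1.94), they had the smallest unadjusted p among higher genes without the batch term, though none passed, and reads of Gm and Vmn2r genes may come from relatives. Ratios were 39.6 (13.1 to 195) for Igsf5, a tight junction protein, 27.1 (8.87 to 135) for Slc15a3, a peptide transporter, and 20 (5.11 to 172) for Ccnb1ip1, a meiotic ligase. Igsf5, Slc15a3 and Ccnb1ip1 were not near-silent in MB, with 915, 88 and 376 summed counts in control and 928, 178 and 677 in knockdown. Their MT ratios rest on the MT control library, where they had 3, 3 and 2 counts. Tnmd, a tendon membrane protein, rose by 5.16 (0.165 and 5.99 CPM) and Kcnmb1, a potassium channel subunit of smooth muscle, by 4.22 with the batch term (edgeR, adjusted p = 0.000219 and 0.000329). Smooth muscle markers were not called as a list (camera, adjusted p = 0.574), though Cnn1 rose by 3.34 (5.29 and 53.4 CPM), Tagln by 1.31, Lmod1 by 1.12 and Actg2 by 0.98. The list median of 0.654 was at percentile 100 of random lists, with 5 of 11 rising and 2 falling.

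**Figure D3:**
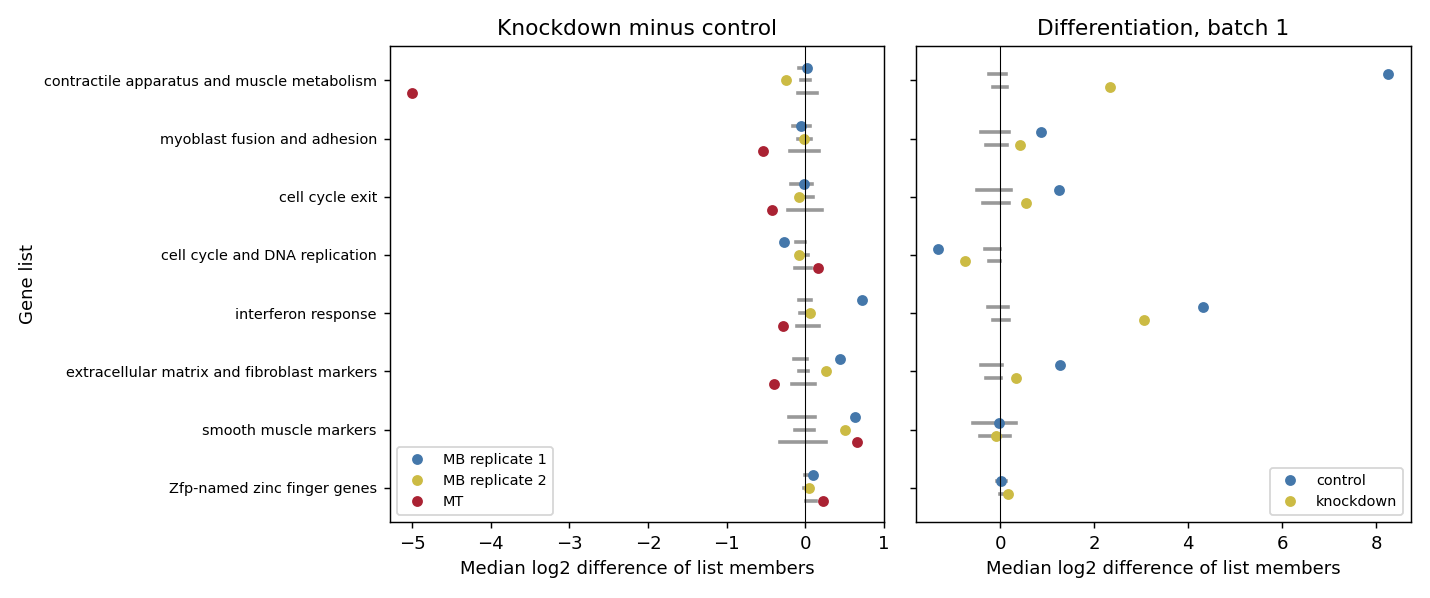
Median log2 difference of 8 gene lists, left for knockdown minus control in the MB replicate 1 pair (blue), the MB replicate 2 pair (yellow) and MT (red). The right panel gives MT minus MB of batch 1 in control (blue) and knockdown (yellow) cells, with grey bars for the central 95% of 10000 random lists matched on expression.

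Control cells turned on muscle genes during differentiation, together with matrix and interferon genes, and turned down the cell cycle. Chrng, the fetal acetylcholine receptor subunit, went from 0.242 and 8.68 CPM in MB to 331 CPM in MT, Ckm from 0.194 and 2.52 to 200 CPM, and Myog from 1.28 and 33.8 to 818 CPM. Without a batch term edgeR quasi-likelihood called 0 genes (Benjamini-Hochberg, smallest adjusted p = 0.0522), while 4174 had unadjusted p under 0.05 (2215 higher, 1959 lower) and DESeq2 called 2370 (1285 higher, 1085 lower). In the fit with it 7398 were called, of which 3670 rose and 3728 fell, and 2294 and 1159 of these changed at least 2-fold.

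The smallest unadjusted p without the batch term, none passing, belonged among higher genes to Trim30a, Pygm, Asb2, a ubiquitin ligase subunit of muscle, Itgb1bp2 and Gm43302, which rose by 4.22, 5.68, 5.41, 6.07 and 7.88 with the batch term. Lower genes of this kind were Hmga1, a chromatin protein of dividing cells (-3.01), Alcam, an adhesion molecule (-2.58), Gpd2, a mitochondrial dehydrogenase (-2.08), Slc16a11, a monocarboxylate transporter (-3.22), and Gja1, a gap junction protein (-1.86). Muscle genes rose by more with the batch term than against MB_shCtrl replicate 2 alone. Chrng rose by 10.64, Ckm by 10.01, Mymk by 10.07 and Mymx by 9.37, against 5.25, 6.31, 6.08 and 5.30 without MB_shCtrl replicate 1. Myod1 rose by 4.59 (adjusted p = 0.0241, edgeR with batch term; 2.91 without MB_shCtrl replicate 1). Genes with more counts in MT control than in either MB control library included Hfe2, a muscle coreceptor (94.4 CPM in MT, 0.0726 and 2.55 in MB). Its log2 change was 5.21 without MB_shCtrl replicate 1 and 10.3 without MB_shCtrl replicate 2. Others of this kind were Nmrk2, a nicotinamide riboside kinase (65.1 CPM in MT), and Mybpc1, a myosin-binding protein (54.7; 0.0242 and 0.858 in MB). So were Rbm24, a splicing regulator of muscle (48.7; 0 and 1.19 in MB), Adamtsl2, a matrix glycoprotein (44.7), the cardiac myosin Myh6 (42.6), Cox8b, a respiratory chain subunit (23.3), and Cap2, an actin regulator (16.6). Prl2c2 (-8.42) and Prl2c3 (-8.25), hormone genes whose near-identical copies share reads, fell. So did Ptprn, a secretory granule phosphatase (-6.60, and -3.74 without MB_shCtrl replicate 1), Itgb7, an integrin (-6.12, and -5.17 without it), Acsbg1, a fatty acid enzyme (-5.95, and -4.54), and Prr9 (-5.56, and -2.43). Without the same library Prl2c2 and Prl2c3 stood at -6.21 and -6.35.

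Contractile genes rose as a list in control cells (camera, adjusted p = 1.63e-27; 0.899 with an estimated correlation). Of 78, 72 rose and 0 fell (73 and 0 adjusted over the list alone), with a median of 8.25 within batch 1 (8.31 with counts under 3 set at 3). Interferon genes rose as a list (camera, adjusted p = 1.57e-36; 0.899 with an estimated correlation). Of 55, 53 rose and 1 fell (54 and 1 adjusted over the list alone), with a median of 4.31 (4.37 with the floor). Irf7, the master factor of the response, rose by 6.96, Iigp1 by 8.21 (10.7 without MB_shCtrl replicate 1) and the deubiquitinase Usp18 by 7.40 (10 without it). Cell cycle genes fell as a list (camera, adjusted p = 1.34e-25; 0.899 with an estimated correlation). Of 72, 67 fell and 2 rose, the same adjusted over the list alone, with a median of -1.32. Kif20a fell by 1.88, the checkpoint gene Mad2l1 by 1.60 and the helicase subunit Mcm5 by 1.58. Matrix genes rose (camera, adjusted p = 5.11e-07; 0.899 with an estimated correlation). Of 43, 26 rose and 8 fell, the same adjusted over the list alone, with a median of 1.27. Col6a1 rose by 2.70 and Dcn, a collagen-binding proteoglycan, by 7.97 (3.17 without MB_shCtrl replicate 1). Each of these batch 1 medians was at percentile 0 or 100 of random lists.

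Cell cycle exit genes rose as a list in control cells (camera, adjusted p = 0.00495; 0.899 with an estimated correlation, 0.0865 with no filter). Of 15, 9 rose and 1 fell (10 and 1 adjusted over the list alone), and the risers include Cdkn1c (log2 change 6.05), Cdkn1a (3.13) and Rb1 (2.03). Fusion genes rose (camera, adjusted p = 0.0113; 0.899 with an estimated correlation, 0.0898 with no filter and 0.0707 without MB_shCtrl replicate 1). Of 26, 17 rose and 2 fell (17 and 3 adjusted over the list alone), including Capn3, a muscle protease (2.72), Dysf (2.56), Ncam1 (2.16) and Jam3 (1.33). Targets of the tumour suppressor p53 were higher (camera, adjusted p = 0.0446; 0.899 with an estimated correlation). Of 37, 12 rose and 7 fell (14 and 7 adjusted over the list alone), and Pmaip1, a death effector, rose by 3.31. That p53 call was lost with no filter (0.194), without MB_shCtrl replicate 2 (0.0808) and with the batch term (0.134, camera). Genes often used as controls fell (camera, adjusted p = 0.0283; 0.899 with an estimated correlation, 0.066 without MB_shCtrl replicate 1). Of 15, 8 fell and 0 rose (8 and 1 adjusted over the list alone), with the actin Actb at -1.12 and the tubulin Tubb5 at -1.20.

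Knockdown cells raised interferon genes and lowered cell cycle genes during differentiation, but raised contractile genes far less than control cells. Tnnt1, a slow troponin, went from 0.739 and 14.9 CPM in MB to 40.5 CPM in MT, where the control reached 428 CPM, and Chrng from 0.232 and 11.6 to 19.3 CPM. Without a batch term edgeR quasi-likelihood called 0 genes (Benjamini-Hochberg, smallest adjusted p = 0.239), 2512 had unadjusted p under 0.05 (1226 higher, 1286 lower) and DESeq2 called 843 (358 higher, 485 lower). The fit with it called 5446, 2736 rising and 2710 falling, with 1407 and 653 changing at least 2-fold. Interferon genes rose as a list (camera, adjusted p = 5.76e-48; 0.899 with an estimated correlation). Of 55, 53 rose and 1 fell, the same adjusted over the list alone, at a batch 1 median of 3.06 (3.17 with the floor). Irf7 rose by 5.58 and Usp18 by 5.86 (8.74 without MB_shKap1 replicate 1). Cell cycle genes fell (camera, adjusted p = 5.21e-23; 0.899 with an estimated correlation). Of 72, 63 fell and 0 rose (66 and 0 adjusted over the list alone), at a median of -0.751, with the nucleotide reductase Rrm2 at -1.97 and Mcm5 at -1.70. Contractile genes rose (camera, adjusted p = 0.00145; 0.915 with an estimated correlation). Of 78, 54 rose and 3 fell, the same adjusted over the list alone, at a batch 1 median of 2.33 (2.47 with the floor). The contractile call was lost with the MT libraries placed in batch 2 (camera, adjusted p = 0.149), a setting added after seeing the data. Without MB_shKap1 replicate 1 the contractile list stood at 0.513 (camera), Tnnt1 at 1.44 in place of 5.86, and Chrng at 0.74 in place of 6.17.

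Matrix genes also rose in knockdown cells (camera, adjusted p = 0.00861; 0.899 with an estimated correlation, 0.0508 with no filter and 0.109 without MB_shKap1 replicate 2). Of 43, 17 rose and 5 fell (18 and 8 adjusted over the list alone), at a median of 0.326, with Dcn rising by 6.38. Control genes fell (camera, adjusted p = 0.0283; 0.899 with an estimated correlation, 0.0833 without MB_shKap1 replicate 1, 0.11 with the MT libraries placed in batch 2). Of 15, 5 fell and 0 rose (6 and 0 adjusted over the list alone), Actb by 0.74 and Tubb5 by 0.64. KAP1 and its partners fell as a list (camera, adjusted p = 0.0296; 0.899 with an estimated correlation). Of 23, 7 fell and 3 rose (8 and 3 adjusted over the list alone). The maintenance methyltransferase Dnmt1 fell by 1.24 and its guide Uhrf1 by 1.34. The list call was lost without MB_shKap1 replicate 2 (0.0925) and with the batch term (0.0914, camera). Mitochondrial genes fell (camera, adjusted p = 0.0283; 0.899 with an estimated correlation). Of 44, 5 fell and 3 rose (5 and 1 adjusted over the list alone), and the call was lost with total library size (0.0543), without MB_shKap1 replicate 2 (0.153) and with the batch term (0.119, camera). Targets of p53 were higher (camera, adjusted p = 0.0446; 0.899 with an estimated correlation), 7 rising and 5 falling, the same adjusted over the list alone. Blood and endothelial markers were higher too (camera, adjusted p = 0.0446; 0.899 with an estimated correlation). Of 10, 3 rose and 0 fell (4 and 0 adjusted over the list alone), among them the macrophage lysozyme Lyz2 (0.38 and 0.162 CPM in MB, 3.05 CPM in MT). Both calls were lost without MB_shKap1 replicate 2 (0.35 and 0.0612), with no filter (0.294 and 0.342) and with the batch term (0.134 and 0.19, camera), and that of the blood markers also with total library size (0.0663).

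The effect of the knockdown differed between stages most for muscle genes, which were low in both MB groups and separated in MT. For the interaction, the MT effect minus the MB effect, edgeR quasi-likelihood without a batch term called 0 genes (Benjamini-Hochberg, smallest adjusted p = 0.848). Unadjusted p was under 0.05 for 825 (282 higher, 543 lower), and DESeq2 called 168 (20 higher, 148 lower). The fit with it called 1722, 630 above and 1092 below 0, with 267 and 722 at least 2-fold, and the share above 0 was 36.6% with TMM scaling and 52.1% with total library size. Pygm (-5.56), Itgb1bp2 (-5.53), Asb2 (-4.37), Cacnb1 (-3.63) and Lzts3 (-2.77) had the smallest unadjusted p below 0. Above 0 these were the growth signal Wnt10b (1.55), Pttg1, a regulator of chromosome separation (1.42), the glutathione transferase Gsto1 (1.36), Tes, a focal adhesion protein (1.29), and Gja1 (1.26), none passing without the batch term. The largest values with it included Myh8 (-8.20, between -10.9 without MB_shCtrl replicate 2 and -6.36 without MB_shKap1 replicate 2) and Ablim3, an actin-binding LIM protein (-7.33). On the other side were the keratin Krt13 (3.90, and 5.32 without MB_shKap1 replicate 2) and Itgb7 (3.72, and 3.14 without MB_shCtrl replicate 1). Mymk was at -5.60 (-8.87 without MB_shCtrl replicate 2, -2.82 without MB_shKap1 replicate 2) and Mymx at -3.94 (-7.20 and -1.05 without the same libraries), and Adam12 and Ncam1 stood at -1.96 and -1.50.

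By list, contractile genes were below 0 in the interaction (camera, adjusted p = 3.9e-31; 0.899 with an estimated correlation), with 64 of 78 called below and 0 above (68 and 0 adjusted over the list alone). Matrix genes (camera, adjusted p = 4.63e-07; 0.899 with an estimated correlation) had 20 of 43 below and 2 above (27 and 2 adjusted over the list alone). Interferon genes (camera, adjusted p = 1.46e-06; 0.899 with an estimated correlation) had 16 of 55 below and 0 above (26 and 0 adjusted over the list alone), and stood at 0.159 without MB_shKap1 replicate 1. Fusion genes (camera, adjusted p = 0.00508; 0.899 with an estimated correlation, 0.0898 with no filter, 0.0719 without MB_shCtrl replicate 1) had 10 of 26 below and 2 above (12 and 4 adjusted over the list alone). Cell cycle exit genes (camera, adjusted p = 0.00491; 0.899 with an estimated correlation, 0.0527 with no filter, 0.108 without MB_shCtrl replicate 1) had 5 of 15 below and 2 above (6 and 2 adjusted over the list alone). Cell cycle genes were above 0 (camera, adjusted p = 6.93e-07; 0.899 with an estimated correlation), 28 of 72 called above and 4 below (30 and 8 adjusted over the list alone).

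Knockdown effects in MB and MT, which share no library, correlated across genes with r = 0.312 (rho 0.209, 56.5% of genes with the same sign), between 0.0631 without MB_shCtrl replicate 2 and 0.364 without MB_shKap1 replicate 2. Compared with MT, the MB replicate 1 pair gave 0.233 (rho 0.235, 58.8% with the same sign) and the replicate 2 pair 0.242 (rho 0.104, 51.3%). For genes with a mean of at least 10 CPM rho was 0.231 and 0.0134, with 59.3% and 49.2% of the same sign. The MB pairs compared with each other gave 0.442 (rho 0.348, 62.4%). In the batch term fit 174 genes rose in both stages, Fat4 and Slc1a6 among them, and 96 fell in both, Il33 and Grem1 among them, where independent calls would give 37.5 and 24.7. Conversely, 61 rose in MB and fell in MT (46.2 if independent), Col6a1 among them, and 17 did the reverse (20). The values under independence are a rough guide only, because both contrasts come from 1 fit and share each gene's dispersion estimate. Control and knockdown differentiation correlated with r = 0.641 (rho 0.662), or 0.73 within batch 1, and with the batch term 1919 genes rose in both and 2015 fell in both. No value under independence is given for these, because both contrasts share the estimate of the batch difference.

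Other lists fixed beforehand were not called in any comparison by camera without the batch term. Adjusted p is given here in the order MB knockdown, MT knockdown, control differentiation, knockdown differentiation and interaction. Myogenic regulators stood at 0.488, 0.0673, 0.569, 0.426 and 0.0804 (camera). Genes of the undifferentiated myoblast state and inhibitors of differentiation stood at 0.493, 0.198, 0.752, 0.569 and 0.356, where 17 of 38 fell and 5 rose in MT knockdown with the batch term (17 and 7 adjusted over the list alone). Imprinted genes, which include known targets of KAP1 in embryos, stood at 0.0893, 0.323, 0.237, 0.925 and 0.0515. Of 49, 20 rose and 8 fell in control differentiation with the batch term, with H19 at 5.58 and the growth factor Igf2 at 8.95 on the log2 scale, against 2.30 and 5.61 without MB_shCtrl replicate 1. In MT knockdown 15 fell and 3 rose, with H19 at -1.89 and Igf2 at -2.79. Germline genes, silenced by KAP1 in other cells, stood at 0.774, 0.461, 0.574, 0.987 and 0.372. Among markers of other cell types, those of osteoblasts and chondrocytes stood at 0.198, 0.384, 0.479, 0.488 and 0.944. Adipocyte markers stood at 0.11, 0.521, 0.925, 0.774 and 0.88, though their MT knockdown median of 0.5 was at percentile 99.6 of random lists. Of these 12 genes, 8 lay above 0 and 4 below in MT knockdown. Neuronal markers stood at 0.0804, 0.239, 0.178, 0.925 and 0.0804. Stress genes of the unfolded protein response stood at 0.435, 0.987, 0.488, 0.23 and 0.696, histone genes at 0.497, 0.359, 0.0804, 0.323 and 0.198, and 3 nuclear-retained RNAs at 0.497, 0.784, 0.358, 0.186 and 0.958. Comparisons in which the remaining lists were not called had adjusted p of 0.0515 or more without the batch term, contractile genes in MB knockdown among them (0.233).

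With the batch term camera called 18 further tests of lists, and 0 of them held with an estimated correlation, where adjusted p was 0.789 or more. That check had little power with 1 residual degree of freedom. In MB knockdown the further calls were contractile genes (lower, adjusted p = 0.0393, 4 of 78 rising and 6 falling, 5 and 8 adjusted over the list alone), imprinted genes (higher, 0.00337) and p53 targets (higher, 0.0261; camera). Contractile medians had opposite signs in the replicate 1 and replicate 2 pairs (0.0252 and -0.244). In the same order imprinted genes were at 0.2 and 0.0522 and p53 targets at 0.22 and 0.013. In MT knockdown mitochondrial genes (0.026), myogenic regulators (0.0283) and genes of the undifferentiated state (0.0283) were lower. For control differentiation histone genes (0.0143), imprinted genes (6.22e-06) and myogenic regulators (0.00977) were higher and neuronal markers lower (0.0277). For knockdown differentiation genes of cell cycle exit (0.00237), histone genes (0.0381), imprinted genes (0.0277) and fusion genes (0.00739) were higher. Because polyA RNA was sequenced, the histone results cover polyadenylated transcripts only. By the interaction imprinted genes (0.000597), myogenic regulators (0.0112) and genes of the undifferentiated state (0.015) were lower, and neuronal markers higher (0.0127).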

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

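The tests of explanations in this part were chosen only after the results had been seen. What drew attention was a difference between groups: the effect of the Kap1 knockdown was not the same in proliferating and differentiated cells. By camera on the interaction, with a preset correlation, contractile genes (adjusted p = 3.9e-31), matrix genes (4.63e-07), interferon genes (1.46e-06), cell cycle exit genes (0.00491) and fusion genes (0.00508) were lower in MT relative to MB, and cell cycle genes (6.93e-07) were higher. Adjusted p was 0.899 for each of these lists with an estimated correlation. By gene, edgeR with the batch term called 1722, with Pygm, Itgb1bp2, Cacnb1 and Myh8 among those below 0, and without it called 0. An example of a change of sign is the matrix gene Col6a1, at 261 and 250 CPM in MB control, 424 and 399 in MB knockdown, 1701 in MT control and 698 in MT knockdown.

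Low contractile expression in the MT knockdown library might be a mixture of the MT control profile with proliferating cells, a matter of scaling, the course of this culture alone, or an effect of the knockdown on differentiation. A plain mixture would keep similar shares of every rise. The rise was taken in CPM from the MB knockdown library of batch 1 to the MT control library, for genes rising by over 1 CPM. Of this rise the MT knockdown library kept a median of 74.2% for interferon genes (quartiles 59.2 and 95.4 over 54 genes). For contractile genes it kept 1.83% (0.935 and 5.3 over 75 genes), which argues against a plain mixture. Cells of the same dish that had received the medium without forming muscle might still give such a profile, which was not measured. A scaling factor moves every gene of a library alike, so it cannot set 1 list apart from the others. The median of the contractile list less that of the other tested genes was -5.1 on the log2 scale, which argues against scaling. By construction this gap is nearly the same under each of 3 scalings, so repeating it added no further test. Whether another culture would differ as much could not be told, because each MT group is 1 library and the contractile list differed by a median of 2.71 on the log2 scale between the MB control replicates alone, so an effect of the knockdown stays a hypothesis that replicate MT cultures would test.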

How the results depend on the processing

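The settings that combine the batch term with another choice, or place the MT libraries in batch 2, were added after seeing the data. Call counts depended on the treatment of the replicate difference and on the tool. The order below is MB knockdown, MT knockdown, control differentiation, knockdown differentiation and interaction. Without a batch term edgeR called 0 genes in each. DESeq2 called 50, 368, 2370, 843 and 168 genes, and edgeR with the batch term called 632, 3344, 7398, 5446 and 1722. Combined with the batch term, DESeq2 called 331, 1542, 4279, 2918 and 961, DESeq2 size factors gave 539, 3211, 7208, 5337 and 1605, total library size 509, 3715, 7384, 5241 and 1764, and no filter 1046, 3740, 7534, 5856 and 2245. With the MT libraries placed in batch 2 the counts were 627, 3343, 7809, 5774 and 1723. The MB libraries fitted alone gave 674 genes with the batch term and 0 without it. Without the batch term, control differentiation had 78 genes with DESeq2 size factors, 582 with no filter, 144 without MB_shKap1 replicate 1, 148 without MB_shKap1 replicate 2 and 0 without either MB_shCtrl library, and knockdown differentiation had 2 with no filter. The batch check behind this is the correlation of 0.762 between the replicate differences of control and knockdown, and simulated counts with such a difference gave the fit without a batch term 0 of 100 changed genes; why single settings differ was not tested otherwise.

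Of 35 list calls, 0 held with an estimated correlation, a check with little power at 2 residual degrees of freedom. DESeq2 size factors kept 34 of them, total library size 33, the batch term 29 and no filter 22. The batch term called 47 in all, 18 of which were not called without it. With the MT libraries placed in batch 2, 31 were kept. Lost were the contractile (0.149), control gene (0.11) and blood marker (0.0724) calls of knockdown differentiation and the cell cycle call of MT knockdown (0.105, camera). The interferon list in MB knockdown ranged from adjusted p = 4.7e-23 (camera, without MB_shKap1 replicate 2) to 0.504 in the opposite direction (without MB_shKap1 replicate 1). Smooth muscle markers in MB ranged from 1.22e-05 (camera, without MB_shCtrl replicate 1) to 0.984 in the opposite direction (without MB_shCtrl replicate 2). Leaving out a library unbalances the batches, and a fit with the batch term and a library left out was not run because no residual degree of freedom remains. For smooth muscle markers both matched MB pairs had medians above 0 (0.63 and 0.505). Replicate 2 less replicate 1 stood at -1.122 in control and -0.594 in knockdown for that list. A fit with a library left out mixes this replicate difference into the MB knockdown contrast. The cause of the changes was not tested further.

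Genes that differ between replicates changed direction in MB knockdown when a library was left out. Cnn1 ranged from -0.97 to 3.23 on the log2 scale, Tagln from -0.00211 to 2.72, Actg2 from -0.40 to 1.79, Myog from -4.69 to 2.54 and Myod1 from -2.67 to 0.013. Trim28, knockdown differentiation, ranged from -0.39 to 0.16 in the same way, was -0.37 with the batch term and 0.14 with the MT libraries placed in batch 2, so no direction is given for it. Trim28 itself was lower after knockdown in MB and MT under every setting.

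The correlation of knockdown effects between MB and MT was 0.312, ranged from 0.0631 to 0.364 with a library left out, and was 0.205 for genes with a mean of at least 10 CPM. That of control and knockdown differentiation was 0.641, ranged from 0.541 to 0.63, and was 0.741 for the same genes and 0.73 with the batch term. The median change of all tested genes in MT knockdown was 0.018 with TMM, -0.023 with DESeq2 size factors and 0.155 with total library size, so small list medians such as that of the Zfp genes (0.22, 0.178 and 0.356) carry that uncertainty while contractile genes (-5.08, -5.12 and -4.94) do not depend on it. In the same order, cell cycle genes in MT knockdown were at 0.154, 0.111 and 0.29 and interferon genes at -0.29, -0.332 and -0.154. Genes often used as controls were at 0.183, 0.141 and 0.32 in MT knockdown, no lower than cell cycle genes and close to Zfp genes. In MB knockdown they were at -0.0297, -0.034 and 0.00188. DESeq2 gave no adjusted p for Myf6 in MT knockdown, and alternatives meant for normalized values were not run because the values are counts.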

Other observations

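The tests in this part were chosen after the results had been seen, except that of liver RNA, which was written down before its values were computed. Some genes differed at least 2-fold in the same direction in all 3 knockdown and control pairs (MB replicate 1, MB replicate 2 and MT): 147 higher and 40 lower, 187 in all, where reversing the sign of 1 pair left 8, 8 or 21. Among those counted at moderate levels were the glutathione transferase Gsta4 (log2 differences 1.73, 1.81 and 2.80), Mcam, a melanoma and pericyte adhesion molecule (2.33, 1.79 and 2.23), and Adam22, a neuronal adhesion protein (2.16, 2.40 and 3.67). So were the matrix proteins Aspn (2.63, 1.23 and 1.85) and Col27a1 (2.16, 2.26 and 1.89), Sfrp2, a Wnt inhibitor (4.02, 2.06 and 1.17), and Sema3f, a guidance cue (2.04, 1.99 and 2.64). Lower throughout were Il33 (-3.69, -3.21 and -4.62), Frmpd1, a scaffold protein (-2.42, -2.49 and -4.15), Msln, a mesothelial surface protein (-2.71, -1.40 and -3.18), Blnk (-2.60, -2.36 and -1.93) and Lgr6, a stem cell receptor (-1.46, -1.63 and -1.23).

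Most genes higher in all pairs were nearly silent in control cells: 111 of 147 (75.5%) had a mean control level under 1 CPM, among them Serpina1d, Cyp2b10, Cdhr2 and Epas1. Choosing genes by their ratio to control can itself favour low control levels, and the share among all tested genes was not computed. For genes lower in all pairs the share under 1 CPM in control was not computed. Their means over all libraries, another measure, ranged from low, such as Gas7 (0.288 CPM), to high, such as Grem1 (126 CPM) and the target Trim28 (297 CPM). A general background of reads might lift such near-silent genes. The 10094 other genes under the same level with a count in a control library, summed, were at 1.12, 1.05 and 0.965 times their control. For the 7879 other genes with 1 to 30 control counts the ratios were 1.15, 1.1 and 1.01. These sums argue against such a background over genes with control reads, and weigh most the genes with more reads. Genes with 0 control counts were left out, so a background confined to them could not be told. Liver RNA as a source of the Serpina1 and Cyp2b genes is argued against by 0 counts of Alb in the knockdown libraries, where Serpina1d had 75, 144 and 462 counts. Reads shared between paralogs could account for part: 14.7% of the 75 near-silent genes with a family-type name shared its stem with another in the set, a check that could not tell because names are a rough guide to paralogs and cover too few of the genes. Release from silencing by KAP1 remains a hypothesis that binding of KAP1 at these genes, not analysed here, would test.

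Both MB groups differed between replicates in muscle genes such as Myog and Mymk and in smooth muscle genes. Replicate 2 might have been further along in differentiation. Of 4275 genes that moved by at least 1 on the log2 scale in batch 1 control differentiation, 58.1% had the same sign in the replicate difference of knockdown cells. Of 2829 that did so in knockdown differentiation, 73.1% had the same sign in that of control cells. Contractile genes went with this, with replicate 2 less replicate 1 at medians of 2.706 in control and 2.24 in knockdown. Interferon genes rose in batch 1 differentiation (4.31 and 3.06) but stood at -0.23 and -1.151 between replicates. Matrix genes rose as well (1.27 and 0.326) but stood at -0.106 and -0.388. The interferon and matrix values argue against differentiation as the whole difference, while a part in it stays open. A difference between batches, in culture or in library preparation, is in line with the correlation of 0.762 between control and knockdown, but the value cannot tell these sources apart, as records of when each library was made would.

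A hypothesis formed from these data is that genes higher in all pairs lie near each other, as they might if knockdown opened stretches of chromatin. Of 127 such genes placed in the gene order of a later genome build, 22 had another within 5 tested genes, where 10000 random sets matched on expression had a median of 10 and a highest value of 31 (permutation p = 0.009). Neighbours included Itln1 with Cd84, Adgrf5 with Mep1a, Tprg with P3h2, and several Serpina1 genes, whose members can share reads. With 1 gene kept per named family, 14 of 120 had a neighbour against a median of 9 in the random sets (permutation p = 0.17, 10000 sets), so the hypothesis was not settled beyond families of related genes.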
